A study of Rattus norvegicus with 9 samples.

How the data were processed

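Lung cells of 9 rats, 3 in each of 3 groups, were profiled by droplet single-cell RNA sequencing. The deposited files hold UMI counts per gene symbol and cell, with 1 matrix per rat, and whole numbers only. Per the file headers the matrices were written by PISA 1.0. Per the submitters' processing notes Cell Ranger 4.3.0 was used, and the genome builds listed are GRCh38 and Rnor_6.0. GRCh38 is a human build, while the files hold rat symbols such as RT1-Db1. The headers and notes differ, so which tool and rat build gave the counts is not settled here. Genes are named by the symbols in the files, and no coordinates are used.

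Matrices were joined by symbol to 30489 genes. Cells with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs were kept, which left 81954 of 82477. Doublets were scored within each library by Scrublet in scanpy 1.11.5. Its automatic threshold failed in 4 libraries, so a fixed score of 0.2 was set after seeing the data, which removed 3320 cells and left 78634. Normalised values of 2000 variable genes, 40 principal components and 20 neighbours gave 58 Leiden clusters at resolution 1.0. Clusters were named from marker genes fixed before the data were examined, with at least 3 markers detected. The scoring limits were set after seeing the data, and 12 clusters stayed unnamed, 7 of them mostly doublets. They held 4.0% of control cells, 1.12% of LPS model cells and 1.35% of YQHYJDF cells.

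Raw counts were summed per library and cell class and tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, R 4.3.3) across all libraries with at least 20 cells of the class. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are given with a standard error computed from the F statistic. Shares of cells were tested with edgeR on cell numbers, with an exact permutation test beside it. Gene lists, 20 fixed before the data were examined, were tested with limma 3.58.1 (camera on voom values, preset correlation 0.01, at least 5 members), with an estimated correlation and fry as alternatives. For the LPS model against control fry gave 104 calls. Of the 111 calls by camera for this comparison, 13 held with an estimated correlation. These were chemokines, chemotaxis, granule and apoptosis genes in endothelial cells, chemotaxis, granule and activation genes in alveolar type 2 cells, chemokines and hypoxia genes in fibroblasts, and chemokines, chemotaxis, MHC class I and antioxidant genes in T and NK cells.

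The rule for named genes was written before the data were examined. It takes the called genes with the largest and smallest log2 fold changes among those with at least 20 CPM in the higher group and no overlap between groups, up to 4 members of each list by smallest p, cell type markers, and, where no gene was called, up to 3 genes of each direction by smallest p. Genes without a symbol, mitochondrial and haemoglobin genes and markers of other classes were left out. The text names part of the genes that the rule allows. The level of a gene was also set against its level in the class where it is highest, with a limit of 10%, since free RNA reaches all droplets.

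Alternatives were other size factors, DESeq2 1.42.0, no low-count filter, only the groups compared, equal cells per library, doublets kept, a 10% mitochondrial limit, coarser and finer clustering, the replicate number as a block, and leaving out each library. Single cell types alone and the 10% limit on levels were added after seeing the data. The tests were tested on simulated data with known changes before use. With LPS model against control simulated, edgeR recovered 10.4%, 41.8% and 92.4% of genes changed 1.5-fold, 2-fold and 4-fold in alveolar macrophages, and in neutrophils 30.3% of those changed 4-fold.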

Results

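Lungs of 9 rats were profiled by droplet single-cell RNA sequencing, 3 rats in each of 3 groups. Untreated rats served as controls. The LPS model group received lipopolysaccharide, a bacterial cell wall component, into the tail vein to produce an acute respiratory distress syndrome model. The YQHYJDF group was given the herbal formula Yiqi Huayu Jiedu by stomach tube before the same injection. The control libraries held 12471 to 13638 deposited cells and 110.8 to 116.9 M UMIs, with a median of 6156 to 6775 UMIs per cell. The LPS model libraries held 6801 to 8662 cells and 85.0 to 92.1 M UMIs, with medians of 7052 to 9365. The YQHYJDF libraries held 6499 to 7284 cells and 80.2 to 87.1 M UMIs, with medians of 8316 to 9858. After filtering, 78634 cells remained, and 22 cell types were named from markers. The edgeR p-values of genes below measure the spread between rats. For shares of cells edgeR pooled the spread over cell types, although shares within a library depend on each other. The p-values of shares therefore do not measure the spread of a single cell type between rats. Those of gene lists with the preset correlation set the members against other genes and do not measure that spread.

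The comparison of the LPS model with controls asks which cells and genes differ after lipopolysaccharide. Cells named monocytes from their markers made up 33.2% ± 6.10 (SD, n = 3) of the cells in the LPS model and 2.67% ± 0.270 in controls, a log2 fold change of 3.64 ± 0.46 (SE; edgeR adjusted p = 8.1e-12). Cluster 1, which holds 3775 of these LPS model cells, scored 1.05 for monocytes and 0.652 for interstitial macrophages, and its top genes include Folr2 and Nr1h3 beside Vcan. Neutrophils rose from 0.274% ± 0.137 to 9.10% ± 5.61 (log2 fold change 5.05), and plasma cells and megakaryocytes or platelets rose as well. T cells fell from 15.7% ± 5.32 to 5.43% ± 2.54, alveolar macrophages from 12.1% ± 2.13 to 5.16% ± 0.943, and alveolar type 2 cells, which make surfactant, from 3.47% ± 0.897 to 1.26% ± 0.515. Alveolar type 1 cells, interstitial macrophages, lymphatic endothelial cells and plasmacytoid dendritic cells were also lower, so that 11 of 22 cell types were called. The exact two-sided permutation p was 0.10 for each of these except lymphatic endothelial cells (0.20), and 0.10 is the smallest that 3 against 3 allows. With shares scaled by TMM over cell types, 7 were called and those of alveolar macrophages, alveolar type 2 cells, interstitial macrophages and lymphatic endothelial cells were not (log2 fold changes -0.77, -1.02, -0.75 and -1.11). The fall of interstitial macrophages was also lost without control 1, control 2 or LPS model 3 (log2 fold changes -1.04, -0.93 and -1.08), and that of lymphatic endothelial cells without control 2 or LPS model 2 (-1.03 and -1.22).

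**Figure D1:**
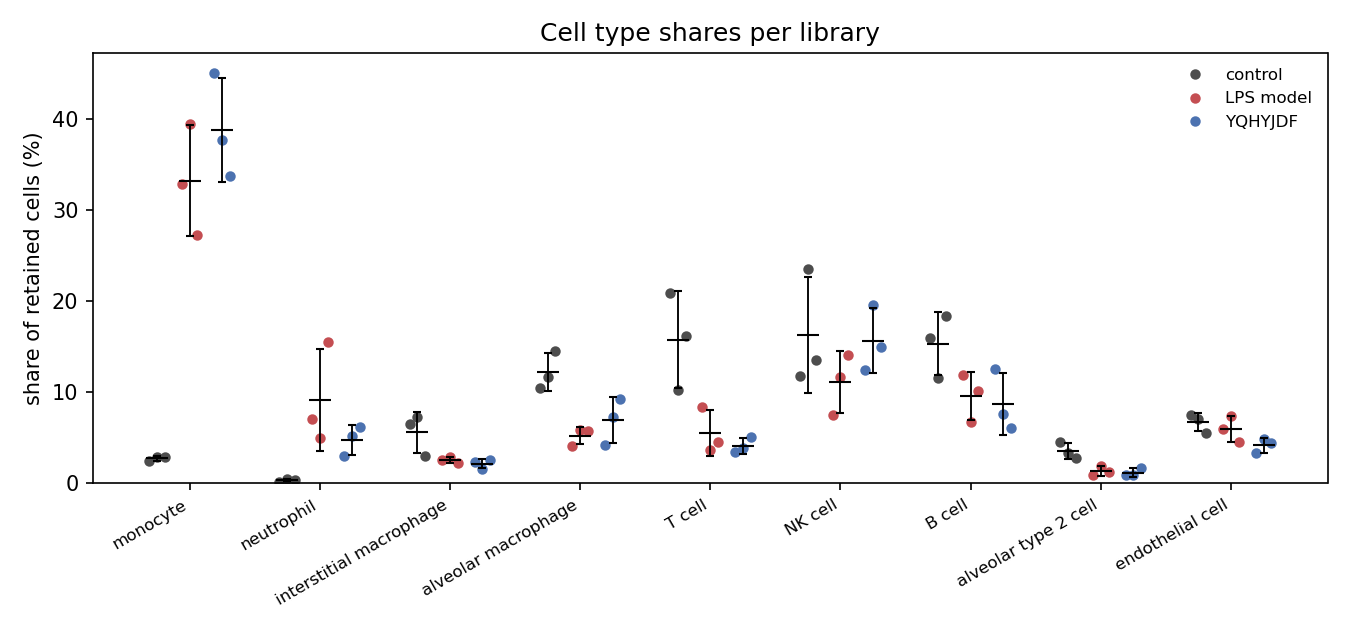
Share of retained cells (%) of 9 cell types on the vertical axis, 1 point per library, with the mean (horizontal line) and SD (bars) of 3 rats per group. Monocytes were near 2.67% in controls and 33.2% and 38.8% in the LPS model and YQHYJDF groups.

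In alveolar macrophages, the resident phagocytes of the air spaces, Il1a, which encodes an inflammatory cytokine, rose from 12.8 ± 2.47 to 101 ± 10.0 CPM (counts scaled to a common library size; SD, n = 3) in the LPS model, a log2 fold change of 2.98 ± 0.30 (SE; adjusted p = 0.000376). Tlr2 and Cd14, receptors for bacterial products, rose by 2.10 and 2.08, and Itgam, an adhesion receptor subunit, by 2.03. Of 34 interferon-stimulated genes measured, 18 rose and 0 fell, among them Oasl at 3.21, and 23 rose when adjusted over the list alone (adjusted p = 1.2e-07 for the list). In LPS model 1, 29 of 32 of these genes were above the mean of the other 2 LPS model rats (median log2 ratio 1.00), and without this rat the list was still called (adjusted p = 3.4e-05). Of 25 chemokines, 10 rose and 1 fell (11 and 2 adjusted over the list alone). The lipid handling list fell, with 6 of 19 members lower and 1 higher (7 and 1 adjusted over the list alone). Cidec, a lipid droplet protein, fell by 2.66 on the log2 scale, Pparg, a regulator of lipid genes, by 0.97, and the lysosomal lipase Lipa by 0.69. These list calls were lost with an estimated correlation, with adjusted p = 0.34 for interferon-stimulated genes, adjusted p = 0.11 for chemokines and adjusted p = 0.25 for lipid handling. In all, 1628 genes were higher and 1466 lower of 14999 tested. Without control 1, control 2 or control 3 the count was 1813, 1960 or 1600, and with equal cells per library 2019. Pparg was not called without control 3 (log2 fold change -0.95, adjusted p = 0.0501, over a range of 0.00075 to 0.0501 across its alternatives). Control cells lay mostly in cluster 5 and cells of LPS-exposed rats in clusters 10 and 46, the latter with 97.3% of its cells from LPS model 1. Summed markers of neutrophils in this class were 535 ± 59.1 CPM in controls and 1735 ± 1420 in the LPS model.

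Monocytes and interstitial macrophages, tested as one class, had 3993 genes higher and 3390 lower of 18126. They made up 2.67% and 5.53% of control cells and 33.2% and 2.46% of LPS model cells, so the fold changes mix both cell types. Of the named genes of this class, 20 kept direction and side of the threshold in monocytes alone, 2 reversed and 1 was weaker. In interstitial macrophages alone 23 kept both. Ccl7 and Ccl12, chemokines that draw monocytes, rose from 55.7 ± 8.65 to 515 ± 217 CPM and from 125 ± 50.8 to 798 ± 196 (SD, n = 3), log2 fold changes of 3.21 ± 0.34 and 2.68 ± 0.31 (SE; adjusted p = 5.68e-05 and 0.000103). Fcgr2b, an inhibitory antibody receptor, rose by 3.20, Hmox1, which degrades haem, by 3.51, and Mmp14, a membrane protease, by 5.62. Of 29 cell cycle genes 27 rose, in the combined list and adjusted over the list alone (adjusted p = 2.2e-10, and adjusted p = 0.096 with an estimated correlation), with Mcm5, a replication helicase subunit, at 1.79. Of 27 heat shock and dissociation genes 22 fell and 2 rose (23 and 2 adjusted over the list alone; adjusted p = 3.1e-09, and adjusted p = 0.096 with an estimated correlation), including the chaperone Hspa1b at -2.86. Selenop, a selenium transport protein, and Ltc4s, which makes leukotrienes, fell, with log2 fold changes of -5.51 and -6.44. Summed neutrophil markers in this class were 370.0 ± 143 CPM in controls and 2738 ± 1408 in the LPS model.

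Of 13 genes of MHC class II antigen presentation, 10 fell and 1 rose in this combined class (11 and 1 adjusted over the list alone; adjusted p = 0.00017, and adjusted p = 0.33 with an estimated correlation). Cd74, the invariant chain, had a log2 fold change of -1.67 and the class II chain RT1-Db1 of -1.71. In monocytes alone 0 of 13 were lower and 1 higher, and Cd74 and RT1-Db1 were at 0.31 and 0.77, neither called. In interstitial macrophages alone 9 of 13 were lower, with Cd74 at -1.32. The heat shock list had 12 of 27 lower in monocytes alone and 20 of 27 in interstitial macrophages alone, and Egr1, called at -1.99 in the combined class, was at -0.01 in monocytes alone. The cell cycle list had 24 of 29 higher in monocytes alone and 2 of 19 in interstitial macrophages alone. Interstitial macrophages alone gave 4260 genes. These separate tests were added after the data were seen. Monocytes lay in cluster 22 in controls and in clusters 1, 8 and 11 in LPS-exposed rats (96.6% of cluster 11 from LPS model 1), and interstitial macrophages in cluster 12 and in cluster 24.

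In neutrophils, 509 genes were higher and 301 lower of 9968, from 2 control libraries of 43 cells each, since the other held 15 cells. These 2 libraries had a correlation of 0.664 with each other, and of 0.640 and 0.627 with the LPS model libraries. Each LPS model library had 0.911 to 0.937 with the others of its group. Control values of single genes are therefore uncertain in this class. The glycolytic enzyme Gapdh rose by 2.84 ± 0.31 (SE; 445 ± 109 CPM, n = 2, to 3170 ± 515, n = 3; adjusted p = 0.000212), Socs3, an inhibitor of cytokine signalling, by 2.07, and Slpi, a protease inhibitor, by 3.06. Retnlg, a granulocyte secretory protein, fell from 1730 to 58.5 CPM (log2 fold change -4.89), the inflammasome sensor Nlrp3 fell by 1.96 and the immediate early gene Fos by 2.17. Of 20 hypoxia and glycolysis genes 9 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 9.1e-07, and adjusted p = 0.095 with an estimated correlation). Ngp, a granule protein, had a log2 fold change of -6.63, but its control values were 1650 and 0 CPM, so its fall rests on control 2. Leaving out control 2 or control 3 leaves 1 control library, and the spread then comes from the other groups, so these values do not show how far a result depends on a rat. Without control 2 Ngp had a fitted value of 6.35 over a control at 0 CPM, which is no bound, and was not called. Il1rn at 1.80 was not called without control 3, nor Cd101 at -4.33 and Cxcr4 at -1.55 without control 2 (log2 fold changes 1.57, -3.62 and -1.26), and the count of called genes was 455 without control 2 and 396 without control 3. It was 458 with only these 2 groups in the fit, 459 with equal cells per library and 1262 with no low-count filter.

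In endothelial cells, which line the blood vessels, Selp, the adhesion molecule P-selectin, rose from 11.7 ± 7.65 to 326 ± 82.8 CPM (SD, n = 3), a log2 fold change of 4.86 ± 0.40 (SE; adjusted p = 1.2e-05). Of 25 chemokines 16 rose and 1 fell (17 and 1 adjusted over the list alone), and this call held with an estimated correlation (adjusted p = 0.026). Of 23 endothelial activation genes 14 rose and 3 fell (17 and 3 adjusted over the list alone; adjusted p = 4.9e-05, and adjusted p = 0.08 with an estimated correlation). Of 20 junction and barrier genes 10 fell and 4 rose (12 and 4 adjusted over the list alone; adjusted p = 0.018, and adjusted p = 0.27 with an estimated correlation). The tight junction protein Cldn5 fell by 2.22 and caveolin Cav1 by 1.23, while Esam and Robo4, both endothelial surface proteins, rose by 1.10 and 1.61. The activation and junction lists moved the same way in leukocyte types tested alone. In T cells, NK cells, monocytes and interstitial macrophages 11 of 19, 14 of 21, 13 of 23 and 12 of 17 activation genes rose. In this order 1, 2, 2 and 1 fell. Of the junction genes 7 of 19, 7 of 20, 6 of 20 and 7 of 18 fell, and 2, 2, 2 and 1 rose. In all 2442 genes were higher and 2061 lower of 13168, and 2995 were called with equal cells per library. Control cells lay mostly in clusters 18 and 23 and those of LPS-exposed rats in cluster 14. Summed neutrophil markers in this class were 76.6 ± 21.6 CPM in controls and 2032 ± 1182 in the LPS model.

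In alveolar type 2 cells, Lcn2, an iron-binding antibacterial protein, rose from 585 ± 266 to 30700 ± 4390 CPM (SD, n = 3), a log2 fold change of 5.72 ± 0.34 (SE; adjusted p = 1.25e-07). All 14 genes of MHC class I and peptide loading rose, in both counts including that adjusted over the list alone (adjusted p = 1.7e-09, and adjusted p = 0.088 with an estimated correlation), among them B2m at 2.00 and Psmb10 at 2.27. The complement component C3 rose by 2.80 and the neutrophil chemokine Cxcl1 by 2.72. The surfactant list was not called. Its member Sftpa1, a surfactant protein, rose by 0.72, and Etv5, a transcription factor of these cells, fell by 1.26. In all 1884 genes were higher and 1683 lower of 11101, and 2098 were called with equal cells per library. Control cells lay mostly in cluster 15 and those of LPS-exposed rats in cluster 42.

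In fibroblasts, the matrix-forming cells, Cfb, a complement factor, rose from 87.3 ± 3.13 to 7640 ± 570.0 CPM (SD, n = 3), a log2 fold change of 6.45 ± 0.25 (SE; adjusted p = 3.74e-08). Timp1, an inhibitor of matrix proteases, rose by 5.91, the cytokine Il6 by 6.34 and the chemokine Cxcl1 by 4.68. Of 33 interferon-stimulated genes 30 rose and 0 fell (31 adjusted over the list alone; adjusted p = 1.9e-12, and adjusted p = 0.16 with an estimated correlation), with Irf7 at 4.52 and Isg15 at 4.86. In LPS model 1, 30 of 33 were above the mean of the other 2 LPS model rats (median log2 ratio 0.68), and without this rat the list was still called (adjusted p = 7.8e-11). Of 25 collagen and matrix genes 16 fell and 6 rose in both counts, that adjusted over the list alone included (adjusted p = 0.0039, and adjusted p = 0.30 with an estimated correlation). Col14a1 fell by 2.14 and Fbn1, a microfibril protein, by 1.36. In all 3018 genes were higher and 2790 lower of 13336. Control cells lay mostly in clusters 25 and 34 and those of LPS-exposed rats in clusters 21 and 37.

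In T and NK cells, Gzmb and Gzma, proteases of cytotoxic granules, rose by 2.45 ± 0.26 and 2.35 ± 0.26 (SE; 522 ± 199 to 2860 ± 224 and 1040 ± 379 to 5280 ± 578 CPM, SD, n = 3; adjusted p = 0.00018 and 0.000223). Lag3 and Tigit, inhibitory receptors, rose by 1.66 and 1.36. Of 22 activation and effector genes 7 rose and 0 fell (8 adjusted over the list alone; adjusted p = 0.018, and adjusted p = 0.28 with an estimated correlation). In NK cells alone 12 of 20 were higher and 3 lower, and in T cells alone 6 of 22 were higher and 2 lower. In all 2753 genes were higher and 2247 lower of 17129, with 3268 called without control 3 and 3037 in T cells alone. T cells lay mostly in clusters 6 and 16 in controls and 13 in LPS-exposed rats, and NK cells in clusters 3 and 36 and in clusters 4 and 38 (97.2% of cluster 38 from LPS model 1).

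In B cells, 8 of 13 MHC class II genes fell and 0 rose in both counts, that adjusted over the list alone included (adjusted p = 9.9e-05, and adjusted p = 0.15 with an estimated correlation). RT1-DOb, a chain of a peptide-loading regulator, fell from 76.6 ± 2.13 to 34.9 ± 8.91 CPM (SD, n = 3), a log2 fold change of -1.16 ± 0.20 (SE; adjusted p = 0.00228). Bcl2, which inhibits cell death, fell by 0.70. Of 15 MHC class I genes 11 rose (12 adjusted over the list alone; adjusted p = 2.8e-06, and adjusted p = 0.065 with an estimated correlation), with Psmb9 at 1.01. In all 1722 genes were higher and 1432 lower of 14048, with 1893 called without control 3 and 5047 under the coarser clustering. Control cells lay mostly in cluster 2 and those of LPS-exposed rats in cluster 7.

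Transcripts of other cell types moved with the groups in the lymphocyte classes. In B cells the summed neutrophil markers were 71.6 ± 22.3 CPM in controls and 1322 ± 1104 in the LPS model, and the summed club cell markers were 10550 ± 1482 and 5273 ± 1702. In T and NK cells the summed neutrophil markers were 76.3 ± 12.5 and 1240 ± 1050. The neutrophil granule and acute-phase list had 12 of 12 genes higher in T cells alone, 11 of 13 in NK cells alone, 10 of 16 in monocytes alone and 11 of 11 in interstitial macrophages alone (median log2 fold changes 4.62, 3.47, 4.36 and 5.58). Saa3 and Lcn2, acute-phase genes, were called higher in all 8 classes, and in B cells they lay at 1.55% and 2.0% of the level in their highest class. The limit of 10% of the highest class was applied in the group where each gene was higher. Called genes at or above it numbered 2255 in alveolar macrophages, 6291 in monocytes and interstitial macrophages, 757 in neutrophils and 4120 in endothelial cells. They numbered 3086 in alveolar type 2 cells, 5335 in fibroblasts, 3903 in T and NK cells and 2388 in B cells. In this order they were 72.9%, 85.2%, 93.5%, 91.5%, 86.5%, 91.9%, 78.1% and 75.7% of the called genes. Of all tested genes 80.3%, 79.3%, 90%, 90.8%, 88.9%, 90.8%, 79.5% and 81.5% lay at or above the limit.

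The comparison of the YQHYJDF and LPS model groups asks what the formula changed in rats given lipopolysaccharide. Between these groups edgeR called 0 genes in each of the 8 classes. At an unadjusted p under 0.05 the counts were 602 in alveolar macrophages, 780 in monocytes and interstitial macrophages, 287 in neutrophils, 804 in endothelial cells, 559 in alveolar type 2 cells, 884 in fibroblasts, 884 in T and NK cells and 717 in B cells. These are 4.01%, 4.3%, 2.88%, 6.11%, 5.04%, 6.63%, 5.16% and 5.10% of the tested genes, where chance gives 5%. Without YQHYJDF 2, edgeR called 1 gene, Reln, in each class except neutrophils. Without YQHYJDF 1 it called 1 in fibroblasts, Aldh1a1, without LPS model 1 it called 1 in monocytes and interstitial macrophages, a gene with no symbol, and without LPS model 2 it called 4 in neutrophils, of which Igha has a symbol. These genes other than Aldh1a1 were chosen after their values were seen. DESeq2 called 14 genes in monocytes and interstitial macrophages, 8 in T and NK cells, 6 in fibroblasts, 2 in alveolar type 2 cells, 1 in neutrophils and 0 in alveolar macrophages, endothelial cells and B cells. The share of tested genes whose groups did not overlap was 7.3% to 9.7% over the classes, where chance gives 10%. In simulated data for this comparison, edgeR recovered 67.2% of genes changed 2.25-fold and 89.6% of those changed 4-fold in alveolar macrophages, and 49.3% and 80.6% in monocytes and interstitial macrophages, where 9.47% of its calls were false. It recovered 56.7% and 89.6% in T and NK cells. In neutrophils it recovered 34.3% and 88.1%, with 9.88% of its calls false. The other classes were not simulated. These simulations changed 67, 67 and 66 genes at once by 2.25-fold, 4-fold and 16-fold. Many changed genes loosen the Benjamini-Hochberg threshold, so these rates do not hold where few genes change. DESeq2's calls in these simulations were false in 24.4% in monocytes and interstitial macrophages and 22.1% in T and NK cells. Genes moved back were those called for the LPS model against control and called in the opposite direction for YQHYJDF against the LPS model. They numbered 0 in both macrophage classes by edgeR, and 4 by DESeq2 in monocytes and interstitial macrophages (1 by edgeR without LPS model 1). In the other 6 classes edgeR gave 0 as well, and DESeq2 4 in fibroblasts, 3 in T and NK cells and 1 each in neutrophils and alveolar type 2 cells. With no low-count filter edgeR gave 140 in endothelial cells, 136 in fibroblasts, 30 in alveolar type 2 cells, 19 in B cells and 14 in neutrophils. It gave 2 in neutrophils with the replicate block or without LPS model 2, and 1 in fibroblasts without YQHYJDF 1. Both comparisons use the LPS model libraries, so opposite signs arise by chance. No chance level was simulated for the other 6 classes, for DESeq2 or for no low-count filter. Their counts therefore do not show a reversal by the formula. For both macrophage classes, in 20 simulations of an unchanged formula group that shared the same LPS model libraries the count was 0, as was the overlap of independent lists. With 0 genes called for the formula that overlap is 0 by construction, and no simulated count can lie below 0. Neither therefore tests the observed 0.

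**Figure D2:**
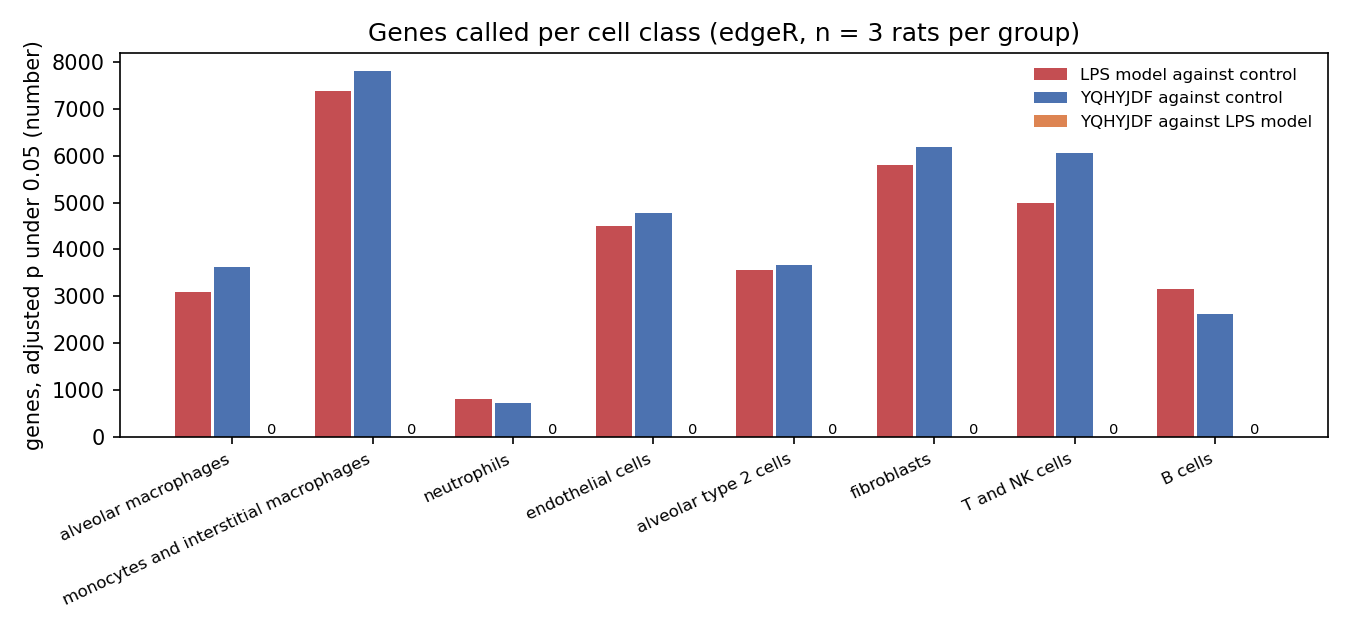
Number of genes called (adjusted p under 0.05, edgeR, 3 rats per group) on the vertical axis for each cell class and comparison. The YQHYJDF and LPS model groups each differed from controls in all 8 classes (3615 and 3094 genes in alveolar macrophages) and from each other by 0 by edgeR.

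In monocytes and interstitial macrophages, Ccl2, a monocyte chemokine, was at 800, 542 and 465 CPM in the YQHYJDF rats and at 1260, 962 and 1070 in the LPS model rats, a log2 fold change of -0.86 ± 0.26 (SE, n = 3; edgeR adjusted p = 0.955). Ccl7 and Ccl12 had log2 fold changes of -0.90 ± 0.31 and -0.76 ± 0.30, with the same adjusted p. In interstitial macrophages alone the 3 values were 0.16, 0.59 and 0.35. In alveolar macrophages the LPS receptor Tlr4 was at 14.4 ± 2.28 and 23.1 ± 1.75 CPM (log2 fold change -0.69 ± 0.15; adjusted p = 0.975). In endothelial cells Edn1, which encodes the vasoconstrictor endothelin, was at 24.9 ± 1.41 and 46.8 ± 3.21 CPM (-0.91 ± 0.20; adjusted p = 0.767). In alveolar type 2 cells Mbl1, a lectin, was at 29.6 ± 6.64 and 66.8 ± 4.52 CPM (-1.15 ± 0.20; adjusted p = 0.267), P2ry4 at -3.19 and Rnase1 at 3.50. In fibroblasts Fgfr4 was at 2.04, Aldh1a1 at 2.17 (2.51 without YQHYJDF 1, where it was called) and Ptges at -0.88. Usp36 was at 0.83 in neutrophils, Ly49s4 at 1.95 and Hp at -0.65 in T and NK cells, and Atg16l2 at 0.57 and Flt1 at -1.15 in B cells. With no low-count filter edgeR called Edn1, Pgm5 (1.31 in endothelial cells with the filter), Mbl1, P2ry4, Rnase1, Fgfr4, Aldh1a1, Ptges and Flt1, and DESeq2 called Rnase10 (-2.43 by edgeR in monocytes and interstitial macrophages), Fgfr4, Aldh1a1, Ly49s4 and Hp. Hp and Flt1 lay at 2.15% and 1.61% of the level in their highest class.

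**Figure D3:**
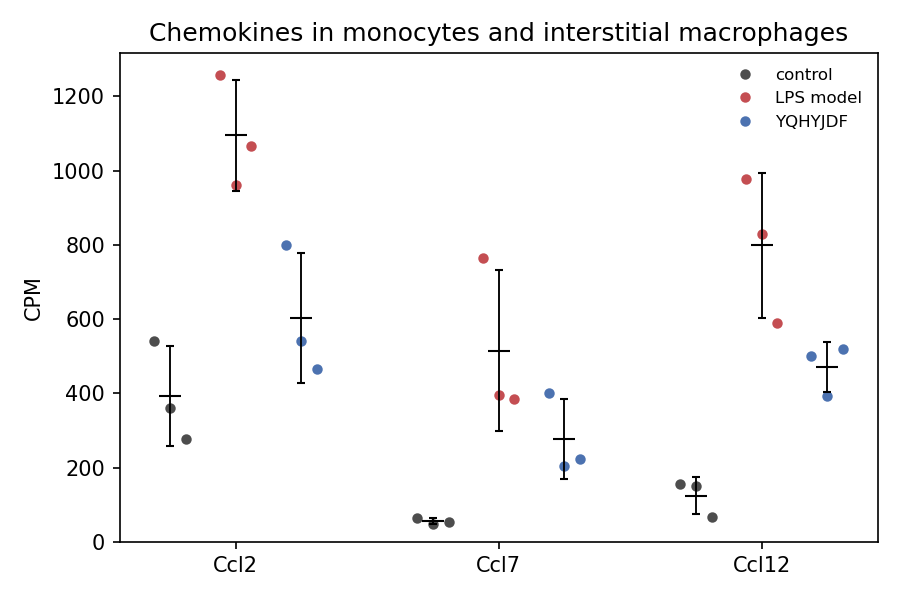
CPM of Ccl2, Ccl7 and Ccl12 in monocytes and interstitial macrophages on the vertical axis, 1 point per library, with mean (line) and SD (bars) of 3 rats per group. Mean Ccl2 was 602 CPM in YQHYJDF rats and 1090 CPM in LPS model rats, a difference that was not called.

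The gene list tests gave 41 calls of 160 between the YQHYJDF and LPS model groups with the preset correlation, 30 lower and 11 higher in YQHYJDF, and 0 with an estimated correlation or with fry. The chemokine list was lower in monocytes and interstitial macrophages (median log2 fold change -0.55, adjusted p = 0.00056, and adjusted p = 0.63 with an estimated correlation), with 0 of 25 members called over all genes and 0 adjusted over the list alone. Its median was -0.49 in monocytes alone and -0.01 in interstitial macrophages alone. In LPS model 1, 18 of 24 of these genes were above the mean of the other 2 LPS model rats (median log2 ratio 0.53), and without this rat the list was still called (adjusted p = 0.0048). Interferon-stimulated genes were lower in alveolar macrophages (median -0.32, adjusted p = 0.00032, and adjusted p = 0.92 with an estimated correlation), and without LPS model 1 this list had adjusted p = 0.89. Without YQHYJDF 2 the number of calls was 26. Without LPS model 1 it was 51, with 27 higher and 24 lower, so that the excess of lower lists was lost. This excess also shrank without LPS model 3 (20 lower, 15 higher) and without YQHYJDF 1 (18 lower, 13 higher). It grew without LPS model 2 (46 lower, 8 higher), so its size depended on the rats included. Of the 22 cell types, 0 differed in share by edgeR and 1, neutrophils, had an unadjusted p under 0.05. Neutrophils made up 4.69% ± 1.66 and 9.10% ± 5.61 (log2 fold change -0.96, adjusted p = 0.52, exact permutation p = 0.30), and 15.5% in LPS model 3. Monocytes made up 38.8% ± 5.74 and 33.2% ± 6.10.

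Against controls, the YQHYJDF group had 3615 genes called in alveolar macrophages and 7798 in monocytes and interstitial macrophages. Without control 1, control 2 or control 3 the first count was 2395, 2396 or 2004, and it was 2223 with equal cells per library. Interstitial macrophages alone gave 4415. Monocytes made up 38.8% and interstitial macrophages 2.10% of the cells in YQHYJDF rats, beside 2.67% and 5.53% in controls. Fold changes of the combined class therefore mix both cell types. In monocytes and interstitial macrophages Ccl7 rose by 2.31 ± 0.33 and Ccl12 by 1.91 ± 0.31 (SE, n = 3; adjusted p = 0.000286 and 0.000611), Hmox1 rose by 2.95, and Selenop, Ltc4s and Kcnt2, a potassium channel gene, fell, with log2 fold changes of -5.59, -6.27 and -6.36. Cd74 had a log2 fold change of -1.55, and of 0.48 in monocytes alone, where it was not called. In alveolar macrophages Ppfia4 fell by 2.90. The list tests gave 105 calls of 160, of which 10 held with an estimated correlation. For the LPS model against control the numbers were 111 and 13. By fry there were 97 calls for YQHYJDF against control and 104 for the LPS model against control.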

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

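The tests on monocytes, interstitial macrophages, T cells or NK cells alone and those limited to genes at 10% or more of their highest class were chosen after the results were seen, and the other alternatives before the data were examined. Over all alternatives 2187 values of named genes for the LPS model against control kept their direction and side of the threshold, 5 were weaker and 3 reversed. For YQHYJDF against the LPS model 408 were the same, 15 passed the threshold (by DESeq2, no filter, or Aldh1a1 without YQHYJDF 1) and 3 reversed. For YQHYJDF against control 239 were the same, 3 weaker and 1 reversed. Reversed were Cd74 (0.31) and RT1-Db1 (0.77) in monocytes alone, Cd74 in monocytes alone for YQHYJDF against control (0.48), Ngp without control 2 (a fitted 6.35 over 1 control library at 0 CPM and so no bound, over a range of -7.51 to 6.35 with 1 library left out), and Ccl2, Ccl7 and Ccl12 for YQHYJDF against the LPS model in interstitial macrophages alone (0.16, 0.59 and 0.35). With equal cells per library, which lowers depth, the called genes for the LPS model against control were 2019 in alveolar macrophages, 459 in neutrophils, 2995 in endothelial cells and 2098 in alveolar type 2 cells, and 2223 in alveolar macrophages for YQHYJDF against control. Interstitial macrophages alone, with fewer cells and another class makeup, gave 4260 and, for YQHYJDF against control, 4415, and T cells alone 3037. The coarser clustering gave 5047 in B cells. In neutrophils no low-count filter gave 1262 and only 2 groups in the fit 458. Leaving out 1 library gave 1600 to 3026 in alveolar macrophages (1813, 1960 and 1600 without control 1, 2 and 3), 396 to 908 in neutrophils (455 without control 2, 396 without control 3, each with 1 control library left, which says nothing about stability), 3268 to 5201 in T and NK cells (3268 without control 3) and 1893 to 3367 in B cells (1893 without control 3). For YQHYJDF against control in alveolar macrophages the range was 2004 to 4524 (2395, 2396 and 2004 without control 1, 2 and 3).

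For YQHYJDF against the LPS model, edgeR's count of 0, with 287 to 884 genes per class at an unadjusted p under 0.05, became 39 in neutrophils, 198 in endothelial cells, 61 in alveolar type 2 cells, 203 in fibroblasts and 32 in B cells with no low-count filter. It became 14 in monocytes and interstitial macrophages, 1 in neutrophils, 2 in alveolar type 2 cells, 6 in fibroblasts and 8 in T and NK cells by DESeq2. Leaving out 1 library gave 0 to 4 in neutrophils (4 without LPS model 2) and 0 to 1 in each other class (1 without YQHYJDF 2, in fibroblasts also without YQHYJDF 1, and in monocytes and interstitial macrophages also without LPS model 1). The count of genes moved back in that class was 4 by DESeq2 and 0 to 1 when 1 library was left out (1 without LPS model 1). Cell types called by share for the LPS model against control were 7 with TMM and 7 of 11 among leukocytes. List tests with an estimated correlation were 13 for the LPS model against control, 10 for YQHYJDF against control and 0 for YQHYJDF against the LPS model. By fry they were 104, 97 and 0 in the same order. With the preset correlation, leaving out 1 library gave 26 to 60 for YQHYJDF against the LPS model (26 without YQHYJDF 2). Without LPS model 1, 27 lists were higher and 24 lower, beside 11 and 30 with all libraries. The cause of these changes was not tested.

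The replicate number as a block changed the count of called genes in neutrophils for YQHYJDF against the LPS model, and that of genes moved back there, from 0 to 2 each. Numbers did not pair the libraries, since 12 of 70 same-number pairs, counted per class, had a correlation over 0.1 (median -0.05, different numbers 0.01). Of 71 combinations of library and class, 19 correlated best with their own number. The same libraries recur across classes, so these counts are not independent.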

Other observations

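The tests of LPS model 1 and of MHC class II genes, and the counts over other splits of the libraries, were chosen only after the results were seen. The test of free RNA and its limit were planned, but its comparison with genes at higher levels was not among the planned criteria.

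Reln, a secreted matrix glycoprotein and marker of lymphatic endothelium, was singled out after its values were seen. In B cells it was at 365, 23.0 and 224 CPM in YQHYJDF 1, 2 and 3, at 18.0, 12.4 and 17.9 in the LPS model rats and at 16.8, 9.41 and 10.6 in controls. In fibroblasts the YQHYJDF values were 365, 18.5 and 212 CPM and in T and NK cells 447, 24.5 and 255. With all libraries edgeR did not call it, and without YQHYJDF 2 it did in these classes, with log2 fold changes of 4.17, 4.46 and 4.46. DESeq2 called it with all libraries in monocytes and interstitial macrophages, alveolar type 2 cells, fibroblasts and T and NK cells (4.01, 3.94, 3.93 and 3.95). In each of the 8 classes YQHYJDF 1 and 3 were above the other libraries, and whether this is free RNA or a difference between rats was not tested. Ly6al in alveolar macrophages, called for YQHYJDF against control (log2 fold change 13.31), was at 0.936, 3.9 and 2430 CPM in YQHYJDF rats and 0.0609, 0.16 and 0 in controls. It was not called without control 1, 2 or 3 (log2 fold changes 13.24, 14.41 and 12.68). The log2 fold change was 4.99 without YQHYJDF 3, where it was still called, over a range of 4.99 to 14.41 with 1 library left out.

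LPS model 1 differed from the other LPS model libraries, with 96.6% to 97.3% of clusters 11, 38 and 46 from this rat. A control label is argued against, since its correlation with the other LPS model libraries was higher than with controls in 8 of 8 classes (mean r across genes 0.931 and 0.786). A label of a formula rat stays open, since its correlation with the other LPS model libraries was higher than with the formula libraries in 4 of 8 classes (0.931 and 0.93). As the cause of its distance from LPS model 2 and 3, such a label is argued against. Its correlation with the formula libraries was below theirs in each class (mean r 0.93, beside 0.964 and 0.968). Stress during dissociation is also argued against, with a median log2 ratio of -0.15 for that list. Of 20 lists, the highest medians were those of collagen and matrix (0.84, but -0.16 in fibroblasts), interferon-stimulated (0.62, but -0.21 in endothelial cells), MHC class II (0.58, but -0.23 in B cells) and inflammatory genes (0.46, above 0 in 8 of 8 classes). Fibroblasts made up 5.67% of the cells of this rat and 3.28% and 2.23% of the others. What raised these lists was not tested.

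MHC class II genes fell in monocytes and interstitial macrophages together. A higher share of monocytes may account for part of this fall, since 0 of 13 were lower in monocytes alone. It does not account for the fall in interstitial macrophages alone, where 9 of 13 were lower. Different clusters hold that class in the 2 groups, so a change of cells cannot be separated from a change within cells.

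Free RNA may explain genes that changed alike in both lymphocyte classes while highest elsewhere. Of 529 such genes under 10% of their highest class, 92.2% lay within 1.5-fold of each other in B cells and T cells. This meets the planned limit for free RNA. Of 1631 genes at 10% or more, 76.4% did too, so that the test could not separate free RNA from a shared change, and the explanation stays open.

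Other splits of the 6 libraries, 10 with the real one, are too few for a share under 0.05. Each other split against controls mixes exposed and control rats, which puts their difference into the spread within groups. Low counts of genes or cell types in those splits are therefore no chance level. For the LPS model against control the real split alone reached its count in each of 7 classes (1 of 10). The highest other count was 1 in alveolar macrophages, monocytes and interstitial macrophages, endothelial cells, T and NK cells and B cells, beside real counts of 3094, 7383, 4503, 5000 and 3154, and 0 in alveolar type 2 cells and fibroblasts, beside 3567 and 5808. For YQHYJDF against control it was 0 in both macrophage classes, beside 3615 and 7798. A real count of 0 is reached by any split, so the shares of splits given for such counts test nothing. For YQHYJDF against the LPS model, with real counts of 0, all 10 splits gave as many, and the highest other count was 3 in monocytes and interstitial macrophages and in T and NK cells, 1 in alveolar macrophages, neutrophils, endothelial cells, alveolar type 2 cells and B cells, and 0 in fibroblasts. For genes moved back 20 of 20 splits gave as many as the real 0, with highest other counts of 1 and 3. The 111 list calls for the LPS model against control were reached by 3 of 10 splits (highest other 113), the 41 for YQHYJDF against the LPS model by 7 (81) and the 105 for YQHYJDF against control by 1 (91). The 11 cell types called by share were reached by 1 of 10 (highest other 0), and the 0 between YQHYJDF and the LPS model by 10 (1). Splits that mix LPS model and control rats thus reached as many list calls as the real split with the preset correlation. Such splits keep part of the group difference, so their list calls are not counts without one.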
